A study of Arabidopsis thaliana with 30 samples.

How the data were processed

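Seed of Arabidopsis thaliana Col-0 was hybridized to 30 one-colour Affymetrix arrays with biotin-labelled RNA, 3 arrays in each of 10 groups. Per the labels' protocols, 80 mg of seed per sample was harvested, dried, stratified for 48 h at 4 °C in the dark on MS medium and then kept at 22 °C in continuous light of 100 µE per square metre and second, and 400 ng of total RNA was labelled. The treatment protocol gives 14 days of drying before the dry seed sample and the design text 15 days. Light and the higher temperature started together, so the groups in light differ from those in stratification by both. Whether the 3 replicates of a group are separate cultures or repeated measurements of one is not given in the sources used here. All p-values below measure only the spread between these samples, which may be technical, and the number of arrays, 3 per group, limits the precision of every value.

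The deposited values are probe set intensities on a linear scale, and the authors had summarized and normalized them before they were deposited. Per the submitters' processing notes MAS5, RMA and Partek were used, but which of them made these values, and in which version, is not given in the sources used here. The values ran from 2.54 to 32818, were all above 0 and had nearly equal upper ranges on every array. Median intensity per array ranged from 11.8 to 19.4 and differed between groups, with group means of 12.3 in freshly harvested seed, 12.4 in dry seed, 11.8, 12.0 and 14.1 at 1, 12 and 48 h of stratification and 14.4, 15.7, 17.2, 18.8 and 19.1 at 1, 6, 12, 24 and 48 h of light. Detection calls were not used here, so no probe set was called absent, and intensities near the floor of each array are reported as they are. No 2 of the columns were identical.

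Of 22810 probe sets 64 controls were set aside and 22746 were tested. In the annotation used here 13513 probe sets name exactly 1 gene (13356 genes), 503 name several and 8730 carry no name. Of the first kind 13436 were found in the reference gene table and 77 were not, and 0 symbols needed updating. Genes without a probe set that names them could not be followed by name, which removed most landmarks of germination and most members of several lists: of 409 list members fixed in 18 lists 87 were named, and of 19 landmark genes only ICL. Searches by words in gene descriptions, also planned, were not run, because the tables used here hold no descriptions.

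Intensities were put on a log2 scale after 16 was added to each. A linear model with 1 mean per group was fitted to all 30 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes), with 20 residual and 1.2052 prior degrees of freedom. Each of the 9 neighbouring pairs of groups was compared, as were 48 h of stratification with dry seed and 48 h of light with 48 h of stratification, 11 comparisons in all. A probe set counted as changed with a Benjamini-Hochberg adjusted p under 0.05 over all tested probe sets of that comparison and a log2 difference of at least 1. Transient probe sets were those higher by this test than both dry seed and 48 h of light at a time point between them, each counted once at its highest such time point, and those lower than both were treated in the same way. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

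Gene lists were tested with camera of the limma package at its preset correlation of 0.01, on the 13356 named genes with 1 probe set each, where at least 5 members were named, and the p-values were adjusted over 88 tests of 8 lists. The lists were storage proteins and oleosins (6 of 17 members named), LEA proteins (14 of 25), photosynthesis and chlorophyll synthesis (10 of 40), ribosome biogenesis (12 of 29), cytosolic ribosomal proteins (8 of 28), cell wall loosening (6 of 18), heat shock proteins and factors (5 of 19) and cold response (7 of 20). A member counted as higher or lower by the probe set test, and the counts were the same in all 88 cases when p was adjusted over the list alone. The other 10 lists had too few named members and are reported as values: gibberellin (4 of 24), light signalling (2 of 21), fatty acid β-oxidation and glyoxylate cycle (4 of 21), cell cycle (3 of 40), root hair (2 of 10), seed coat (2 of 14) and endosperm (2 of 8), with 0 members named for abscisic acid (of 37), mitochondrial import (of 26) and jasmonate (of 12). The comparisons, lists, thresholds and first set of alternatives were chosen before the data were examined.

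Genes were named by a rule. In the comparisons of dry with freshly harvested seed, of 48 h of stratification with dry seed and of 48 h of light with 48 h of stratification, these were the 12 largest rises and 12 largest falls among changed probe sets that name exactly 1 gene and whose 3 arrays in one group all lay above the 3 in the other. In the other steps the 4 largest of each kind were taken, and a largest rise or fall in the text is the largest by this rule. The rule also took the 12 strongest transient probe sets and the 6 strongest of the reverse course, up to 4 members of each list with the largest change in a comparison, and the landmarks. The text leaves some of them out for length, and gene values outside the rule appear only in the closing section.

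Each step was also tested on simulated data of 22746 probe sets in groups of 3. With log2 changes of 1.5 in 100 probe sets 98 to 100% were recovered over the 11 comparisons, with changes of 2.5 in 100 probe sets 99 to 100%, and at most 1 unchanged probe set was called. Of 200 simulated transient probe sets 99.5% were found with 0 false calls. All simulated changes lay above the size threshold, so these shares do not describe changes near it. On the real arrays of dry and freshly harvested seed, exchanged labels gave up to 55 changed probe sets.

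Alternatives to each choice were run 1 at a time: quantile normalization again, median centring of each array, the dimmest 40% of probe sets left out, the replicate number as a block, only the groups compared in the fit, eBayes with an intensity trend, a pseudocount of 1 or 64, and each array of the compared groups left out in turn. For lists the estimated inter-gene correlation, fry in place of camera and the mean of all probe sets of a gene were also tried, and the normalizations, pseudocounts and arrays left out were added for lists after the data were seen. Labels were also exchanged between arrays, in all 10 splits of the 6 arrays of each comparison and in 100 draws for transient probe sets.

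A further 13 lists were written after the annotation was seen, tested with camera in 143 tests and adjusted over these: plastid-encoded photosynthesis genes, plastid-encoded gene expression genes, mitochondrion-encoded genes, tubulins, RNA polymerase subunits, organelle RNA editing factors, the ATG8 family, isocitrate and succinate dehydrogenases, SWEET transporters, tau class glutathione transferases, LSM proteins, UDP-glycosyltransferases and expansins. Lists of mature pollen, tapetum and low oxygen genes were written after the first results were seen, to test explanations, and are described in the closing section.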

Results

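Transcript levels were followed in whole Arabidopsis thaliana Col-0 seed from harvest to 48 h of light on 30 arrays, 3 in each of 10 groups. The groups were freshly harvested seed, dry seed after ripening (0 h), seed after 1, 12 and 48 h of stratification at 4 °C in the dark, and seed after a further 1, 6, 12, 24 and 48 h in continuous light at 22 °C. Light and warmth began together, so a difference between a group in light and one in stratification cannot be assigned to either. Stratified seed was also imbibed, and no group was imbibed without stratification. A difference between dry seed and stratified seed therefore cannot be assigned to water uptake, cold or time. The groups in light share the same light and temperature and differ in time. Values in this section are mean deposited intensity ± SD of 3 arrays, and differences are on a log2 scale after 16 was added to each intensity, with the standard error from limma where one is given. Adding 16 understates the change of genes with low intensity.

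The median intensity of an array rose along the course, from a group mean of 12.3 in freshly harvested seed and 12.4 in dry seed to 14.1 at 48 h of stratification and 19.1 at 48 h of light. Single arrays ranged from 11.8 to 19.4. Replicates correlated at 0.985 or more in dry seed, the group with the lowest value, and at 0.992 to 0.997 in the other groups. Replicate 1 of dry seed lay furthest from its group, with a spread of 0.193 on the log2 scale. The first principal component held 68.6% of the variance and the second 18.1%. The difference between the 3' and 5' probe sets of the actin control ranged from 0.22 to 0.67 over the groups, that of the GAPDH control from -0.41 to 0.02 and that of the ubiquitin control from -0.95 to -0.42.

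**Figure D1:**
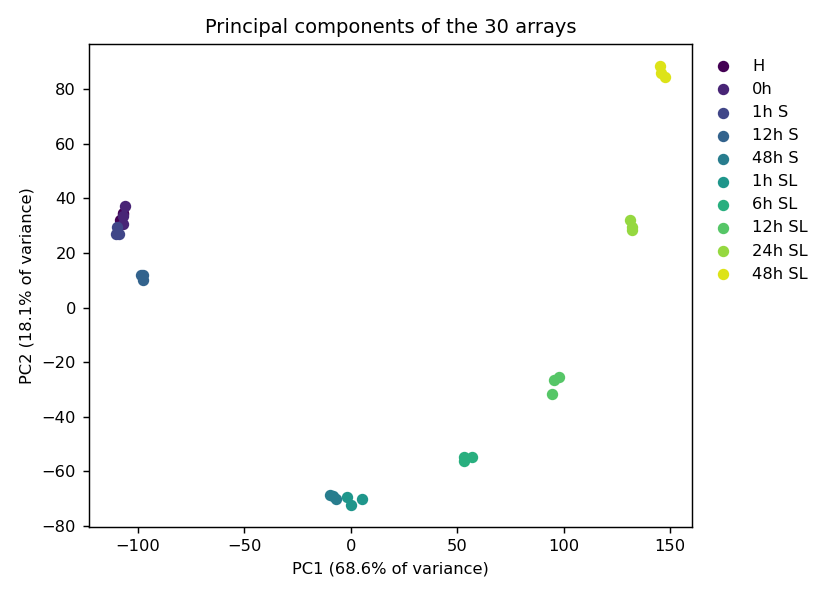
Principal components of all tested probe sets, one point per array, coloured by group, with the share of variance on each axis (68.6% and 18.1%). Freshly harvested seed, dry seed and seed at 1 h of stratification lie close together, and the groups in light spread out in the order of time.

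The 11 comparisons differed widely in size. Few probe sets passed the test between freshly harvested and dry seed (73 of 22746), between dry seed and 1 h of stratification (117) and between 48 h of stratification and 1 h of light (179). The steps from 12 to 48 h of stratification (4186) and from 1 to 6 h of light (1974) were the largest between neighbouring groups. Between 48 h of stratification and 48 h of light 7218 probe sets changed, 31.7% of those tested.

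**Figure D2:**
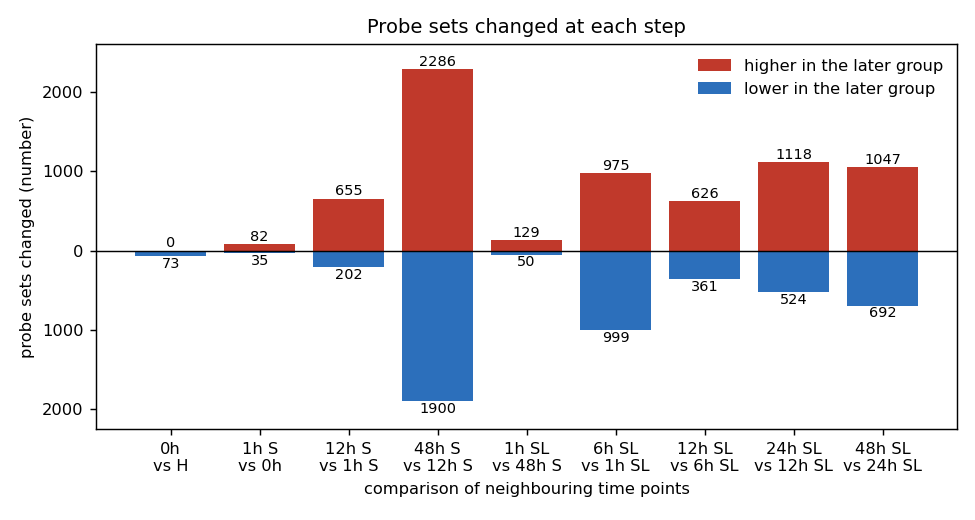
Number of probe sets that changed between neighbouring groups (limma, adjusted p under 0.05 and at least 2-fold), higher in the later group above the zero line and lower below it. The tallest bars are those of 48 h against 12 h of stratification, with 2286 higher and 1900 lower.

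The first comparison asked what changed between harvest and the dry, ripened seed. Every change that passed the test was a loss. The largest was that of AT3G01270, from 492 ± 83.5 to 43.8 ± 15.9 (log2 difference -3.11 ± 0.18, adjusted p = 4.87e-11). AT4G02250 fell from 149 ± 7.01 to 9.63 ± 5.05, AT3G28830 from 112 ± 25.9 to 5.50 ± 0.67 and AT3G28750 from 217 ± 9.77 to 24.8 ± 7.29. RALFL26 (AT3G25170), a gene of the RALF family of secreted peptides, fell from 199 ± 79.2 to 12.3 ± 1.38. Over all 73 lowered probe sets the median intensity was 98.4 in freshly harvested seed and 12.3 in dry seed, and it stayed low afterwards, at 12.7 after 1 h and 6.34 after 12 h of stratification.

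Transcripts typical of the mature seed did not pass the test over the same interval. The oleosin gene OLEO5 (AT3G01570), whose product coats oil bodies, had 12779 ± 792 before and 13362 ± 533 after, the dehydrin gene LTI30 (AT3G50970) 13583 ± 589 and 12795 ± 799, and the isocitrate lyase gene ICL (AT3G21720) 10928 ± 196 and 10346 ± 485, with no call for any of them. No member of the 8 gene lists tested changed. The 12 ribosome biogenesis genes were lower as a list, at a mean of -0.11 (camera, adjusted p = 0.0109), with RH7 (AT5G62190) at 659.9 ± 60.2 and then 583 ± 172. That call had an adjusted p = 0.113 with an estimated correlation and 0.0953 without replicate 1 of dry seed. The cell wall loosening list had a mean of 0.03 with a test direction of down (adjusted p = 0.956).

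Of the 73 probe sets lowered in dry seed 35 fell by at least 4-fold. limma called 0 probe sets higher, 364 probe sets passed on adjusted p alone in either direction, and 2511 had an unadjusted p under 0.05. The count was 28 with only the groups compared in the fit, where RALFL26 had an adjusted p = 0.104, 39 with dim probe sets left out, 133 with a pseudocount of 1 and 38 with a pseudocount of 64.

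Few genes were higher after the first hour of stratification than in dry seed, and 2 of the 4 largest rises were those of plastid genes. Transcripts of psbC, a plastid gene of photosystem II, rose from 146 ± 81.9 to 681 ± 240.0 (2.18 ± 0.40, adjusted p = 0.00104) and those of psaJ, of photosystem I, from 213 ± 202 to 720.0 ± 51.0. The mean of 69 plastid probe sets was higher by 0.62 at 1 h but ranged by 2.14 between the arrays of dry seed and by 1.40 between those of 1 h, and the lists of plastid genes were not called with an estimated correlation (adjusted p = 0.661 and 0.633). The mitochondrial gene nad2 of respiratory complex I fell from 87.5 ± 25.8 to 13.1 ± 1.43. Mitochondrial genes as a set were not lower: the centred log2 mean of 16 of them was 0.92 to 1.06 on the arrays of dry seed and 0.97 to 1.22 on those of 1 h. Among nuclear genes NERD (AT2G16485) rose from 22.1 ± 6.63 to 148 ± 15.66 and LEA25 (AT2G42560), of the late embryogenesis abundant (LEA) proteins, from 2022 ± 1097 to 7630.4 ± 546. AT1G64560 fell from 143 ± 43.5 to 27.6 ± 17.1. With only the groups compared in the fit psbC had an adjusted p = 0.145, psaJ 0.245, nad2 0.0545, LEA25 0.137 and AT1G64560 0.12, and nad2 fell by 0.96 with a pseudocount of 64, short of the size threshold.

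As lists, the LEA genes were higher after 1 h of stratification by a mean of 0.33 and a median of 0.14 (camera, adjusted p = 0.00184, and adjusted p = 0.191 with an estimated correlation), with LEA25 the only one of 14 that passed on its own. Its listmate AT5G44310, at 6935 ± 1633 and 11589 ± 285, did not. The ribosome biogenesis list rose by a mean of 0.27 (adjusted p = 0.00266, and adjusted p = 0.0753 with an estimated correlation), with 1 of 12 members called, NOP2A (AT4G26600), from 25.9 ± 5.41 to 70.4 ± 15.9. The difference of NOP2A, 1.04, was 0.98 without replicate 1 of dry seed, 0.99 without replicate 3 of dry seed, 0.91 without replicate 3 of 1 h of stratification and 0.82 after quantile normalization. Heat shock genes had a mean of 0.02 beside a negative median of under 0.01 in size, and cold response genes a mean of -0.11 with a test direction of up, neither called. The 117 changed probe sets comprised 82 higher and 35 lower, of which 6 and 2 moved by at least 4-fold, and 3552 passed on adjusted p alone. Of the changed, 70.1% were higher, and 56.5% after quantile normalization. The count was 212 without replicate 3 of dry seed, 9 with only the groups compared, 345 with a pseudocount of 1 and 40 with a pseudocount of 64.

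Between 1 and 12 h of stratification a set of genes went from near the floor to high intensity. AT3G19680 rose from 10.3 ± 0.168 to 4185 ± 398 (7.31 ± 0.17, adjusted p = 3.65e-19), AT4G10270 from 20.12 ± 4.53 to 4404 ± 279 and AT2G38240 from 12.8 ± 3.45 to 1108 ± 111. ZAT10 (AT1G27730), a zinc finger transcription factor gene of the cold response list, rose from 553 ± 25.3 to 4019 ± 24.9. The largest falls were those of AT2G38820, from 3428 ± 73.8 to 402 ± 41.7, and AT3G30460, from 209 ± 34.2 to 12.2 ± 4.17. HSP15.7 (AT5G37670), a small heat shock protein gene, fell from 1087 ± 274 to 458 ± 41.9 and the light-harvesting gene LHCB4.1 (AT5G01530) from 173 ± 25.8 to 58.9 ± 6.46, the latter with a difference of -0.94 and uncalled with a pseudocount of 64.

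Of the lists at 12 h of stratification, cold response was higher by a mean of 0.51, carried by ZAT10, the only one of 7 members called, so that the median was 0.09 (camera, adjusted p = 0.00693). COR27 (AT5G42900), at 365 ± 40.6 and then 583 ± 90.6, did not pass. Ribosome biogenesis was higher by 0.19 with 0 of 12 members called (adjusted p = 0.00943), and the heat shock list was lower at a mean of -0.59 with 1 of 5 (adjusted p = 0.0331). Ribosome biogenesis had an adjusted p = 0.11 with an estimated correlation, and heat shock an adjusted p = 0.329 with an estimated correlation and 0.0714 without replicate 3 of 1 h of stratification. The lists of cytosolic ribosomal proteins (-0.02) and cell wall loosening (-0.03) had negative means with a test direction of up and were not called. In all, 857 probe sets changed, 655 higher and 202 lower, 208 and 25 of them by at least 4-fold, and 482 with a pseudocount of 64.

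In the second part of stratification, from 12 to 48 h, transcripts of ribosome biogenesis and ribosomal protein genes rose. All 12 ribosome biogenesis genes rose (mean 1.99, camera adjusted p = 7.10e-11), among them NHP2 (AT5G08180), of the particles that modify ribosomal RNA, from 398 ± 32.6 to 3363 ± 146, NOP58-2 (AT3G05060) from 666 ± 43.2 to 3707 ± 208 and BOP1 (AT2G40360) from 432 ± 11.9 to 2232 ± 138. Of 8 cytosolic ribosomal protein genes 7 rose (mean 2.19, adjusted p = 4.28e-09), such as RPL9D (AT4G10450) from 178 ± 59.7 to 3054 ± 346 and RPL7B (AT2G01250) from 1129.7 ± 88.6 to 6159.5 ± 659. Cell wall loosening genes rose in 5 of 6 cases, the expansin gene EXPA8 (AT2G40610) from 15.5 ± 0.38 to 689.9 ± 129 and EXPA15 (AT2G03090) from 10.8 ± 1.31 to 232 ± 52.8. The single largest rise was that of XTH19 (AT4G30290), a xyloglucan endotransglucosylase gene, from 11.1 ± 0.175 to 1737 ± 104 (6.02 ± 0.10, adjusted p = 8.30e-22).

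Of the 655 probe sets that had risen at 12 h 296 fell over the same step. ZAT10 fell from 4019 ± 24.9 to 13.2 ± 2.02, the largest fall, and AT3G19680 from 4185 ± 398 to 45.5 ± 3.80. All 5 heat shock genes fell, HSP26.5 (AT1G52560) from 2210.2 ± 69.3 to 62.5 ± 5.13, and 10 of 14 LEA genes, AT3G22490 from 4818 ± 337 to 142 ± 8.25. Storage protein and oleosin genes fell in 4 of 6 cases, such as AT1G03890 from 1455 ± 194 to 230.3 ± 9.73, and cold response genes in 3 of 7, such as COR28 (AT4G33980) from 2749 ± 147 to 759 ± 49.9. Photosynthesis genes as a list did not change (mean 0.01, adjusted p = 0.804), though LHCB4.2 (AT3G08940) fell from 51.2 ± 9.15 to 14.9 ± 4.85 (with a pseudocount of 64, -0.55 and uncalled). The kinase gene AUR2 (AT2G25880) fell from 114 ± 10.3 to 11.6 ± 4.13.

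Camera called the heat shock list lower at a mean of -2.75 (adjusted p = 1.47e-04), the LEA list at -1.93 (adjusted p = 3.16e-07), storage at -1.34 (adjusted p = 0.00373) and cold response at -1.65, beside a median of -0.54 (adjusted p = 0.00424), and cell wall loosening higher by 2.02 (adjusted p = 2.56e-04). Storage had an adjusted p = 0.089 with an estimated correlation, cell wall loosening 0.0716 and heat shock 0.087. Changed probe sets numbered 4186, of which 2286 were higher and 1900 lower, with 647 and 583 of at least 4-fold and 2640 in all with a pseudocount of 64. The median difference of all probe sets in this step was -0.01, and -0.11 after each array was centred on its median.

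Over stratification as a whole, 48 h against dry seed, 21.3% of the probe sets tested changed. This comparison holds the uptake of water as well as the cold. The largest rise was that of AT4G30650, from 7.97 ± 0.615 to 1538 ± 141 (6.02 ± 0.14, adjusted p = 6.69e-20), followed by the carboxypeptidase-like gene scpl35 (AT5G08260), from 23.0 ± 6.86 to 2253 ± 299.9, and XTH19, from 15.2 ± 3.39 to 1737 ± 104. The calreticulin gene CRT1b (AT1G09210), of the endoplasmic reticulum, rose from 8.65 ± 1.14 to 649 ± 66.5. AT5G39520 fell most, from 1384 ± 262 to 11.3 ± 4.33, then AT5G05220, from 3075 ± 221 to 50.1 ± 2.76, and HSP26.5, from 3528 ± 39.3 to 62.5 ± 5.13.

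Against dry seed 11 of 12 ribosome biogenesis genes were higher, NOP2A at 531 ± 12.7 after 25.9 ± 5.41 and YAO (AT4G05410) at 866 ± 33.4 after 89.2 ± 18.5, as were 7 of 8 cytosolic ribosomal protein genes, RPL4D (AT5G02870) at 4106 ± 150.4 after 703 ± 106, and 5 of 6 cell wall loosening genes, EXPA8 at 689.9 ± 129 after 13.6 ± 3.78. Lower were 5 of 5 heat shock genes, with HSP15.7 at 34.3 ± 6.03 after 1072 ± 126, 10 of 14 LEA genes, with LEA25 at 182 ± 34.1 after 2022 ± 1097, 4 of 6 storage genes, with OLEO3 (AT5G51210) at 171 ± 9.58 after 640.2 ± 66.9, and 3 of 7 cold response genes, with ZAT10 at 13.2 ± 2.02 after 529.7 ± 45.3. LHCB4.1 and LHCB4.2 fell, to 18.7 ± 3.55 from 179 ± 28.9 and to 14.9 ± 4.85 from 117 ± 14.2, while the other 8 photosynthesis genes did not pass. Of the lists too small to test, the gibberellin receptor gene GID1C (AT5G27320) fell from 51.4 ± 7.63 to 11.9 ± 2.47, and the light signalling genes HYH (AT3G17609) and SPT (AT4G36930) rose, from 25.3 ± 2.76 to 145 ± 17.7 and from 15.6 ± 4.40 to 76.3 ± 6.43. With a pseudocount of 64 the differences of GID1C (-0.60) and SPT (0.82) were too small to be called. ICL, of the glyoxylate cycle, had 10346 ± 485 and then 18995 ± 471, a difference of 0.88 that fell short of the size threshold.

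By camera the lists of ribosome biogenesis (mean 2.45, adjusted p = 4.89e-11), cytosolic ribosomal proteins (2.04, 9.73e-08) and cell wall loosening (1.92, 7.64e-04) were higher after stratification, cell wall loosening with an adjusted p = 0.089 with an estimated correlation. Those of LEA proteins (-1.78, 1.18e-04), heat shock (-3.31, 0.0011), storage (-1.41, 0.0187) and cold response (-1.24, 0.0254) were lower. LEA had an adjusted p = 0.11 with an estimated correlation, heat shock 0.117, storage 0.152 and cold response 0.0709. Photosynthesis was not called (adjusted p = 0.943). The probe sets that changed over stratification were 4846, with 2974 higher and 1872 lower, of which 999 and 665 moved at least 4-fold, and 3163 in all with a pseudocount of 64. Over stratification the median difference of all probe sets was -0.04, and -0.12 after median centring.

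**Figure D3:**
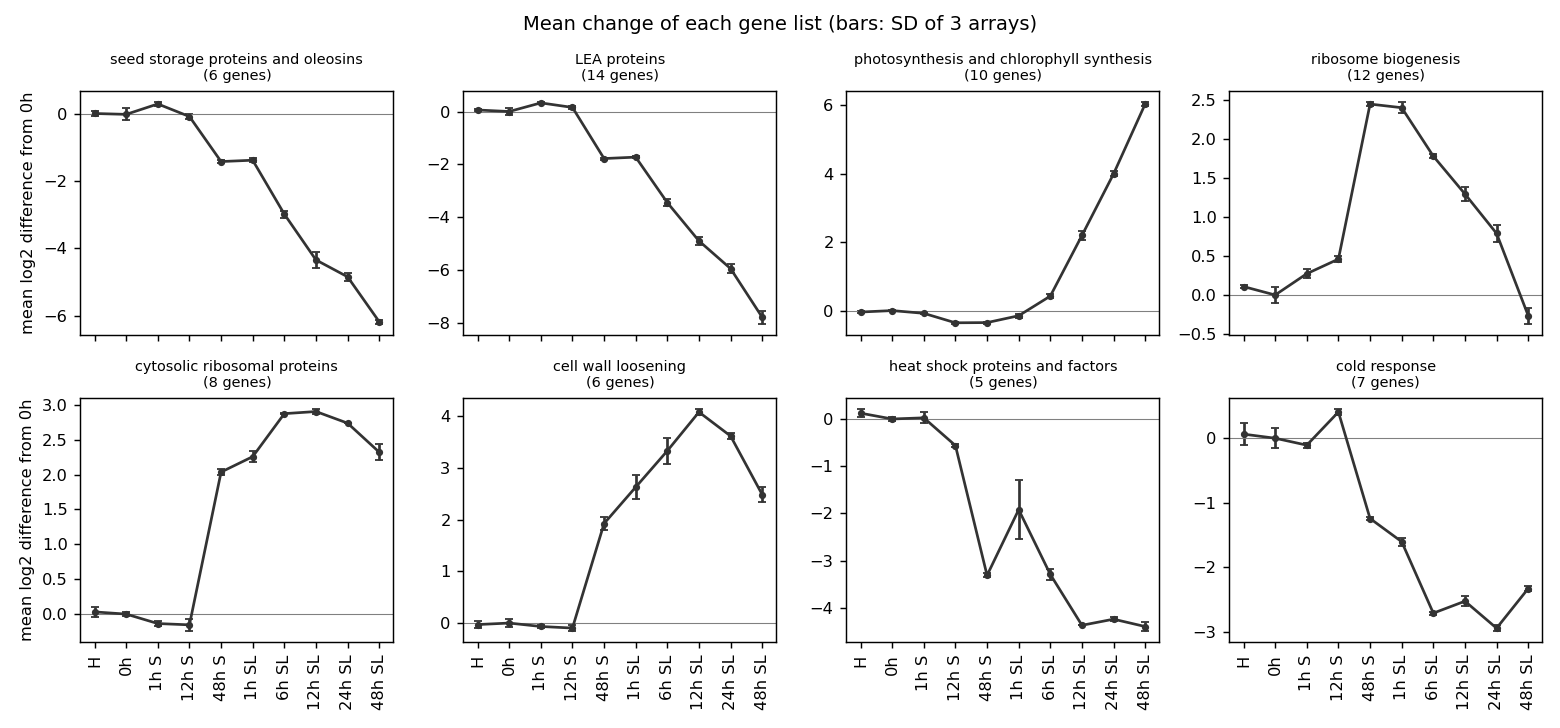
Mean log2 difference from dry seed of the members of each of the 8 lists tested, by group in order of time, with bars for the SD of 3 arrays. Ribosome biogenesis peaks late in stratification, with a mean of 2.45 at 48 h, and photosynthesis rises through the light period, to 6.03 at 48 h of light.

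The first hour of light and warmth after stratification raised genes that respond to heat. HSP15.7 rose from 34.3 ± 6.03 to 291 ± 149 and HSP26.5 from 62.5 ± 5.13 to 317 ± 146. AT3G19680, already high at 12 h of stratification, rose again from 45.5 ± 3.80 to 1242 ± 446 (4.30 ± 0.17, adjusted p = 6.20e-14), AT1G54050 rose from 67.4 ± 4.18 to 1709.5 ± 781 and AT1G14200 from 20.2 ± 1.85 to 688 ± 206. Falling genes included AT1G54120, from 314 ± 43.5 to 62.2 ± 13.7, AT2G28400, from 619.6 ± 17.5 to 142 ± 36.5, and the cold response gene COR28, from 759 ± 49.9 to 293 ± 71.2. With only the groups compared in the fit HSP15.7 had an adjusted p = 0.053 and HSP26.5 0.0702.

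Lists called after 1 h of light were heat shock, higher by a mean of 1.39 with 3 of 5 members (camera, adjusted p = 2.59e-10), cell wall loosening, higher by 0.70 with 2 of 6 (adjusted p = 1.01e-08), cytosolic ribosomal proteins, higher by 0.22 with 0 of 8 (adjusted p = 8.48e-05), photosynthesis, higher by 0.20 with 0 of 10 (adjusted p = 0.0021), and cold response, lower at -0.36 with 1 of 7 (adjusted p = 0.00209). RPS21C (AT3G53890), at 3051 ± 31.0 and then 4196 ± 88.1, and LHCB4.1, at 18.7 ± 3.55 and then 32.2 ± 2.08, did not pass on their own. Of the members called, ROF2 (1.47), EXPA15 (1.11) and XTH16 (1.01) had 0.93, 0.96 and 0.67 without replicate 1 of 1 h of light, short of the size threshold, as had EXPA15 without replicate 1 (0.92) and XTH16 without replicate 3 (0.86) of 48 h of stratification. LEA genes had a mean of 0.05 and a median of -0.04, not called. Of the 179 probe sets that changed 129 were higher and 50 lower, 48 and 2 by at least 4-fold. The count was 116 with only the groups compared, 295 with a pseudocount of 1 and 101 with a pseudocount of 64.

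Between 1 and 6 h of light storage and LEA transcripts fell. The dehydrin gene LTI30 fell from 6595 ± 459 to 81.4 ± 18.18 (-6.10 ± 0.11, adjusted p = 2.19e-20), OLEO5 from 8266 ± 134 to 2129.9 ± 111 and LEA76 (AT3G15670) from 14689 ± 2186 to 2926 ± 217. Of the genes raised in the first hour AT1G14200 fell back to 18.0 ± 4.35, AT3G19680 to 45.3 ± 6.08 and HSP26.5 to 58.6 ± 4.21, while HSP15.7, at 291 ± 149 and then 145 ± 9.75, did not pass (it was called, at -1.11, without replicate 2 of 1 h of light), and neither did XTH16, at 170.1 ± 85.5 and then 209.7 ± 22.1. Among the largest rises of the step, the carboxypeptidase-like genes scpl20 (AT4G12910) and scpl25 (AT3G02110) rose from 82.3 ± 15.4 to 1975 ± 368 and from 80.96 ± 42.9 to 1102 ± 132, and the subtilase gene SBT1.3 (AT5G51750) from 22.4 ± 2.24 to 427 ± 52.6. MCM7 (AT4G02060), of the helicase that opens DNA for replication, rose from 6.09 ± 0.543 to 96.3 ± 3.19. The receptor gene GID1A (AT3G05120) fell from 182 ± 22.6 to 70.6 ± 9.96 and HYH from 103 ± 14.6 to 16.1 ± 4.48, with GID1A at -0.87 and uncalled under a pseudocount of 64.

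All 8 lists were called in this step. LEA (mean -1.72, 10 of 14 lower, camera adjusted p = 8.58e-12), storage (-1.61, 5 of 6 lower, 9.29e-06), ribosome biogenesis (-0.62, 4 of 12 lower, 8.47e-05), heat shock (-1.37, 2 of 5 lower, 7.79e-04) and cold response (-1.11, median -0.28, 3 of 7 lower and 1 higher, 0.00437) fell, heat shock with an adjusted p = 0.112 with an estimated correlation. Cytosolic ribosomal proteins (0.62, 1 of 8 higher, 4.39e-05), cell wall loosening (0.70, 1 of 6, 0.0139) and photosynthesis (0.57, 5 of 10, 0.0177) rose. Cell wall loosening had an adjusted p = 0.201 with an estimated correlation and photosynthesis 0.104. LHCB4.1 rose from 32.2 ± 2.08 to 158 ± 11.1, EXPA9 (AT5G02260) from 73.01 ± 3.13 to 353 ± 90.05 and COR47 (AT1G20440) from 4.45 ± 0.212 to 76.2 ± 17.7, while BRX1-1 (AT3G15460), of ribosome assembly, fell from 1802 ± 71.6 to 786 ± 24.8. Probe sets higher numbered 975 and lower 999, 1974 in all, with 133 and 212 of at least 4-fold and 1047 in all with a pseudocount of 64.

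From 6 to 12 h of light the photosynthesis genes rose as a list. The largest rise of a single gene was that of PYK10 (AT3G09260), a β-glucosidase of endoplasmic reticulum bodies, which went from 165 ± 13.4 to 5737 ± 671 (4.98 ± 0.07, adjusted p = 2.37e-22). Also among the largest rises, the body protein gene NAI2 (AT3G15950) went from 24.6 ± 3.18 to 614 ± 103 and the lectin gene JAL34 (AT3G16460) from 6.62 ± 0.561 to 405 ± 13.4. PORB (AT4G27440), of chlorophyll synthesis, rose from 8.63 ± 0.161 to 183 ± 33.7 and RCA (AT2G39730), which activates Rubisco, from 103 ± 8.73 to 492 ± 101. The LEA gene M10 (AT2G41280) fell from 4802 ± 301 to 237 ± 97.9, M17 (AT2G41260) from 6757 ± 674 to 438 ± 92.1 and the storage globulin gene PAP85 (AT3G22640) from 6992 ± 588 to 617 ± 183. Cold response genes moved both ways, COR27 up from 20.7 ± 4.30 to 120.1 ± 17.3 and LTI30 down from 81.4 ± 18.18 to 11.5 ± 3.90 (-0.94 and uncalled with a pseudocount of 64).

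Photosynthesis rose in 10 of 10 members by 12 h of light (mean 1.77, camera adjusted p = 1.31e-19) and cell wall loosening in 2 of 6 (0.75, 0.00173, and adjusted p = 0.107 with an estimated correlation). LEA fell in 9 of 14 (-1.45, 4.99e-12), storage in 3 of 6 (-1.37, 3.63e-05), heat shock in 4 of 5 (-1.08, 4.70e-04) and ribosome biogenesis as a list alone, with 0 of 12 called (-0.49, 2.97e-05) and BRX1-1 at 786 ± 24.8 and then 443 ± 8.60. With an estimated correlation heat shock had an adjusted p = 0.105. Cold response had a mean of 0.19 and a median of -0.01, not called (adjusted p = 0.743), and cytosolic ribosomal proteins had a mean of 0.03 (adjusted p = 0.547). The step changed 987 probe sets, 626 higher and 361 lower, 99 and 82 by at least 4-fold, with 1692 at a pseudocount of 1 and 471 at a pseudocount of 64.

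At 24 h of light, against 12 h, AT4G01700 rose from 15.3 ± 1.28 to 1902 ± 112 (5.94 ± 0.07, adjusted p = 1.46e-24) and AT1G04040 from 5.31 ± 0.171 to 1077 ± 138. Genes of photosynthesis went on rising, PSAE-1 (AT4G28750), of photosystem I, from 62.0 ± 2.46 to 833 ± 58.2 and PRK (AT1G32060), of the Calvin cycle, from 48.8 ± 8.72 to 343 ± 26.7. The defensin-like genes PDF2.1 (AT2G02120) and LCR67 (AT1G75830) fell, from 683 ± 83.4 to 29.6 ± 11.9 and from 6539 ± 863 to 509 ± 94.9. Of the cell wall genes EXPA15 fell from 1098 ± 96.7 to 119 ± 6.68 and EXPA8 from 1806 ± 305 to 451 ± 56.7, while XTH16 (AT3G23730) rose from 519 ± 28.3 to 1472 ± 57.3. The kinase gene AUR1 (AT4G32830), which acts at mitosis, rose from 4.68 ± 0.163 to 32.8 ± 5.77, and HYH from 51.7 ± 6.63 to 190.1 ± 18.0. AUR1 had a difference of 0.49 with a pseudocount of 64, which was not called.

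Camera called 3 lists at 24 h: photosynthesis, with 8 of 10 members higher (mean 1.80, adjusted p = 3.10e-14), LEA, with 6 of 14 lower (-1.05, 2.77e-05), and ribosome biogenesis, lower with 0 of 12 called (-0.51, 4.23e-04), such as GAR1 (AT3G03920) at 3110.4 ± 112 and then 1648 ± 88.0. The LEA list had an adjusted p = 0.089 with an estimated correlation. The lists of storage (mean -0.50, 2 of 6 lower, adjusted p = 0.21), cold response (-0.42, 2 of 7 lower, 0.589), cytosolic ribosomal proteins (-0.17, 0.325), cell wall loosening (-0.46, median 0.10, 0.859) and heat shock (0.13, median -0.01, 0.859) were not called. PAP85 fell from 617 ± 183 to 177 ± 71.0 and COR27 from 120.1 ± 17.3 to 9.64 ± 1.68. Among 1642 changed probe sets 1118 were higher and 524 lower, with 338 and 82 of at least 4-fold, 2649 in all with a pseudocount of 1 and 861 with a pseudocount of 64.

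In the last step, from 24 to 48 h of light, the largest rise was that of TT3 (AT5G42800), the dihydroflavonol reductase gene, from 5.34 ± 0.159 to 1026 ± 77.5 (5.61 ± 0.05, adjusted p = 1.04e-27) while UF3GT (AT5G54060), a glycosyltransferase gene of anthocyanins, rose from 4.05 ± 0.0742 to 516 ± 129. Of the root hair list, too small to test, the expansin genes EXPA18 (AT1G62980) and EXPA7 (AT1G12560) rose from 15.1 ± 7.58 to 619.7 ± 111 and from 19.8 ± 3.50 to 268 ± 45.2. Outside that list AT4G26010 rose from 39.3 ± 12.2 to 2430.3 ± 263. EXPA8 fell from 451 ± 56.7 to 14.8 ± 2.63, scpl20 from 2408 ± 154 to 113 ± 17.5 and LEA4-1 (AT1G32560) from 656 ± 126 to 20.8 ± 22.1. The dehydrin genes LTI30 and COR47 rose, from 13.7 ± 3.24 to 165 ± 10.7 and from 282 ± 23.9 to 856 ± 35.2. ICL did not pass, at 24426 ± 1011 and then 14540.0 ± 1679, while the lipase gene SDP1 (AT5G04040) fell from 248 ± 39.6 to 106 ± 12.1 (-0.87 and uncalled with a pseudocount of 64).

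Photosynthesis rose again in 10 of 10 members at 48 h of light (mean 2.04, camera adjusted p = 3.88e-14), PSAN (AT5G64040) from 352 ± 45.5 to 2305 ± 301. Falls were called for LEA in 7 of 14 (-1.84, 3.16e-07), ribosome biogenesis in 8 of 12 (-1.05, 1.00e-08), storage in 3 of 6 (-1.34, 0.00209), cell wall loosening in 2 of 6 (-1.13, 0.00601) and cytosolic ribosomal proteins with 0 of 8 (-0.42, 0.00638). Storage had an adjusted p = 0.0753 with an estimated correlation, cell wall loosening 0.152 and cytosolic ribosomal proteins 0.0968. Cold response (0.61, adjusted p = 0.0767) and heat shock (-0.16, adjusted p = 0.86) were not called. Of ribosome biogenesis WDR12 (AT5G15550) fell from 379.8 ± 27.3 to 129 ± 26.4 and BOP1 from 1386 ± 169 to 558 ± 23.8. The changed probe sets of this step were 1739, with 1047 higher and 692 lower, 352 and 113 of them by at least 4-fold, 2840 with a pseudocount of 1 and 898 with a pseudocount of 64.

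Across the whole light period, 48 h of light against 48 h of stratification, storage and LEA transcripts fell and those of the photosynthesis list rose. PYK10 rose from 5.33 ± 0.195 to 14531 ± 2033 (9.40 ± 0.07, adjusted p = 4.08e-29), AT4G23670 from 8.42 ± 0.704 to 7787 ± 673, PORB from 11.1 ± 2.26 to 3889 ± 467, LHCB4.1 from 18.7 ± 3.55 to 4447 ± 393 and RCA from 29.1 ± 4.26 to 5100.0 ± 744. M17 fell from 18528 ± 681 to 5.82 ± 0.157 (-9.73 ± 0.20), PAP85 from 22568 ± 235 to 11.2 ± 2.75 (-9.70), M10 from 16764 ± 660.2 to 5.26 ± 0.237, LCR67 from 18067 ± 794 to 17.8 ± 7.85 and OLEO5 from 9283 ± 836 to 16.6 ± 0.815.

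All 10 photosynthesis genes rose, and 6 of 6 storage, 13 of 14 LEA and 12 of 12 ribosome biogenesis genes fell, such as YAO from 866 ± 33.4 to 72.9 ± 5.64 and PES (AT5G14520) from 4654 ± 315 to 632 ± 46.8. The remaining lists were divided. Cell wall loosening had 3 of 6 higher, such as XTH16 from 71.1 ± 15.0 to 962 ± 118, and 1 lower, EXPA8 from 689.9 ± 129 to 14.8 ± 2.63. Cold response had 1 of 7 higher, COR47 from 4.096 ± 0.16 to 856 ± 35.2, and 3 lower, such as LTI30 from 9267 ± 423 to 165 ± 10.7. Heat shock had 1 of 5 higher, ROF2 (AT5G48570) from 8.52 ± 1.16 to 43.6 ± 17.2 (0.56 and uncalled with a pseudocount of 64), and 3 lower, such as HSP17.6C (AT1G53540) from 168 ± 16.2 to 5.15 ± 0.394. Of 8 cytosolic ribosomal protein genes RPL9D fell, from 3054 ± 346 to 1296 ± 244, and RPS21C rose, from 3051 ± 31.0 to 6458 ± 665. The difference of RPS21C, 1.07, was 0.99 without replicate 2 of 48 h of light and 0.85 after median centring.

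In the lists with too few named members for a test, cell cycle genes rose, MCM7 from 5.47 ± 0.196 to 179.6 ± 15.4, AUR1 from 4.69 ± 0.128 to 129 ± 16.1 and AUR2 from 11.6 ± 4.13 to 245 ± 54.7. The gibberellin receptor gene GID1A fell from 278 ± 32.1 to 27.8 ± 4.58, and of lipid breakdown SDP1 fell from 598 ± 56.2 to 106 ± 12.1 and AIM1 (AT4G29010) from 1145 ± 167 to 492 ± 93.2, while ICL, at 18995 ± 471 and then 14540.0 ± 1679, did not pass. EXPA18 and EXPA7, of root hairs, rose from 5.65 ± 0.0854 to 619.7 ± 111 and from 5.20 ± 0.0632 to 268 ± 45.2. Of the seed coat pair TT3 rose from 5.71 ± 0.106 to 1026 ± 77.5 and BAN (AT1G61720) stayed near the floor, at 4.11 ± 0.0521 and 4.05 ± 0.108. The endosperm genes AGL62 (AT5G60440) and IKU2 (AT3G19700) did so too, at 5.63 ± 0.12 and 4.86 ± 0.102 in light.

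By camera photosynthesis was higher by a mean of 6.38 (adjusted p = 1.80e-11), and LEA (-6.01, 1.38e-09), storage (-4.78, 1.43e-04) and ribosome biogenesis (-2.71, 1.18e-07) were lower over the light period. Cytosolic ribosomal proteins (0.29, adjusted p = 0.0874), heat shock (-1.08, 0.218), cold response (-1.09, 0.218) and cell wall loosening (0.56, 0.303) were not called. Higher probe sets numbered 3456 and lower ones 3762, of which 1674 and 1360 moved by at least 4-fold, and the total was 4695 with a pseudocount of 64. For all probe sets the median difference over this period was -0.02, and -0.24 after median centring.

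**Figure D4:**
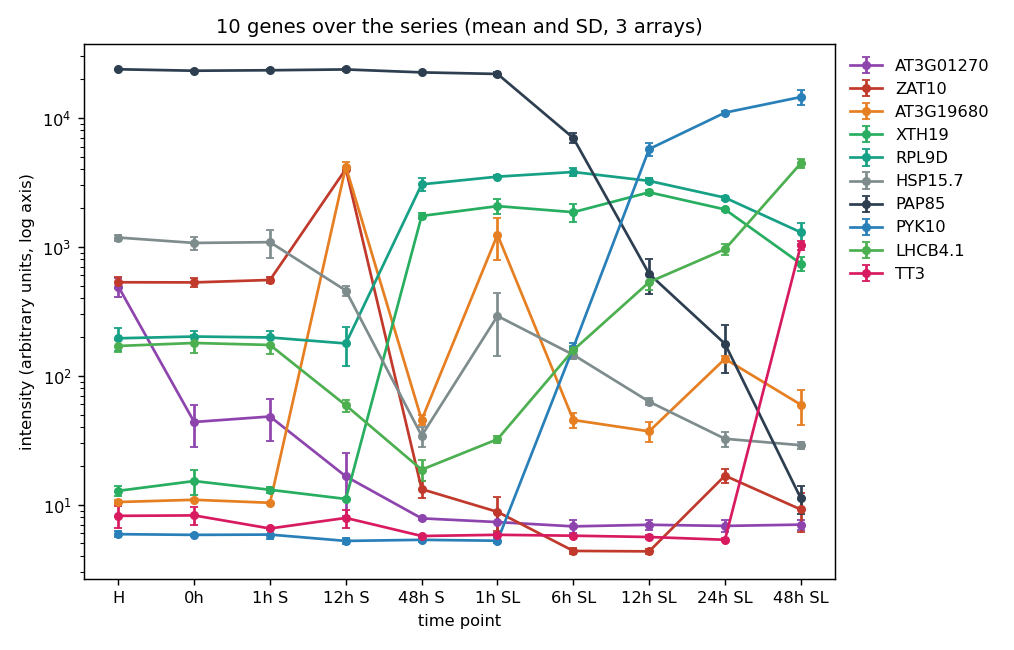
Mean intensity of 10 named genes by group on a log axis, with bars for the SD of 3 arrays. AT3G19680 is high at 12 h of stratification (4185 ± 398) and again at 1 h of light, and PYK10 reaches 14531 ± 2033 at 48 h of light.

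A last question was which transcripts were raised only between the dry seed and the seedling. Of these transient genes scpl44 (AT1G43780) peaked at 12 h of light, at 3931 ± 99.5 beside 7.65 ± 0.395 in dry seed and 17.41 ± 14.4 at 48 h of light, and EXPA8 at the same time, at 1806 ± 305 beside 13.6 ± 3.78 and 14.8 ± 2.63. AT3G19680 and AT2G38240 peaked at 12 h of stratification, at 4185 ± 398 and 1108 ± 111, with 59.6 ± 17.8 and 6.17 ± 0.224 at 48 h of light. The reverse course, low in between, was that of AT4G13180, from 808 ± 68.8 in dry seed to 12.2 ± 0.926 at 12 h of light and 350.5 ± 29.6 at 48 h. The other 8 of the 12 strongest transient probe sets and 5 of the 6 strongest of the reverse course name no gene here.

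In total 2431 probe sets were transiently higher, with their peak at 1 h (39), 12 h (387) or 48 h (715) of stratification or at 1 h (409), 6 h (419), 12 h (345) or 24 h (117) of light. Transiently lower were 501, with 5, 15 and 126 at the same times of stratification and 94, 99, 135 and 27 at those of light. Each peak time is that of the highest mean and was not tested against its neighbours. Of the 387 with a peak at 12 h of stratification 279 were called higher than at 1 h, and 275 were called lower at 48 h. Beside the 409 peaks at 1 h of light, only 129 probe sets in all were called higher there than at 48 h of stratification. A pseudocount of 64 gave 1526 transiently higher and 214 transiently lower, and a pseudocount of 1 gave 865 transiently lower.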

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

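Among the tests in this part, those of gene lists with normalization, pseudocount or arrays changed were chosen after the results were seen. No called gene named in the text and no called list changed direction under any alternative run. Of 9303 values of named genes under an alternative 9143 stayed on their side of the thresholds, 112 were no longer called and 48 were newly called. For lists the same numbers were 1272, 32 and 16 of 1320.

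The pseudocount moved the counts of all 11 comparisons. With a pseudocount of 64 the changed probe sets were 38 for dry against freshly harvested seed, then 40, 482 and 2640 at the steps of stratification, 101, 1047, 471, 861 and 898 at those of light, 3163 over stratification and 4695 over the light period, with 1526 transiently higher and 214 transiently lower. A pseudocount of 1 gave 133 for dry seed, 345 at 1 h of stratification, 295 at 1 h of light, 1692 at 12 h, 2649 at 24 h, 2840 at 48 h and 865 transiently lower. A larger pseudocount shrinks differences at low intensity by its construction, and 49 calls of named genes ended with 64.

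With only the 6 arrays compared in the fit the counts were 28 for dry seed, 9 at 1 h of stratification and 116 at 1 h of light, and 19 calls of named genes ended. Fewer arrays leave fewer degrees of freedom in every comparison. The fit to all arrays also assumes 1 spread for all groups. The mean spread was 0.161 in dry seed, 0.130 in freshly harvested seed and 0.125 at 1 h of stratification, against 0.087 to 0.109 in the later groups. The p-values of the first 2 steps may therefore be too small. Leaving out dim probe sets gave 39 for dry seed, as fewer probe sets were tested. The other counts with these settings, and all counts with quantile normalization, median centring, an intensity trend or the replicate number as a block, lay within 1.5 times the count reported.

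Same-numbered arrays did not go together (mean r of -0.0093 over 135 pairs, 20 of them above 0.1, and 7 of 30 arrays closest to their own number), so the numbers were not taken as pairs. With the number as a block the counts differed from those reported only at 1 h of light (178), over the light period (7216) and for transiently higher probe sets (2430), and no call of a named gene or list changed.

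Leaving out 1 array gave 90 to 212 probe sets at 1 h of stratification, the lowest without replicate 1 and the highest without replicate 3 of dry seed. For dry seed it gave 72 to 86 probe sets and 0 to 1 gene lists, 0 without replicate 1 of dry seed. At 1 h of light the range was 138 to 206. For lists at 12 h of stratification it was 2 to 3, and the heat shock list was lost without replicate 3 of 1 h.

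Lists depended on the correlation assumed between genes. With an estimated inter-gene correlation 30 of 52 calls held and 22 did not: the calls numbered 0 for dry seed, 0 at 1 h, 1 at 12 h and 4 at 48 h of stratification, 5 at 6 h of light, 3 at 48 h of light and 2 over stratification. With fry they were 0 for dry seed, 5 at 12 h of stratification, 7 at 24 h of light and 8 over the light period. With dim probe sets left out ribosome biogenesis was no longer called at 12 h of stratification, photosynthesis and cell wall loosening at 6 h of light and cytosolic ribosomal proteins at 48 h of light, while cold response was newly called higher at 48 h of light (mean 0.86). Quantile normalization also ended the call of cytosolic ribosomal proteins at 48 h of light, and a pseudocount of 1 ended heat shock at 12 h of stratification and cold response over stratification. Cytosolic ribosomal proteins were called higher over the light period with quantile normalization and with median centring. Except where a construction is named above, the cause was not tested.

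Signal over background limits these arrays. The median intensity of an array was 11.8 to 19.4 beside a highest value of 32818, and in 7 of the 10 groups the pseudocount of 16 exceeded the median intensity, so differences of dim genes are understated.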

Other observations

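The gene lists of the next 2 paragraphs were chosen after the annotation was seen, and of the tests further on, those of the scaling of the arrays, of the plastid share and of the control probe sets were chosen after the result was seen. The lists of mature pollen, tapetum and low oxygen genes were also written after the first results were seen, to test explanations of patterns found in these same data. Most tubulin genes named here rose over the light period. TUA6 went from a mean intensity of 329.7 at 48 h of stratification to 6206 at 12 h and 5645 at 48 h of light, TUB1 from 7.12 to 732 and TUB5 from 7.59 to 682. Of 7 tubulin genes 5 were higher and 1, TUA1, lower over the light period (mean difference 2.98, camera adjusted p = 0.00545, and 0.176 with an estimated correlation), and the rise from 6 to 12 h was called with both (4 of 7 genes, 1.07, 9.60e-08 and 0.0102). Of the RNA polymerase subunits NRPA2 went from 237 to 797 late in stratification and to 79.7 at 48 h of light. As a list they were higher over stratification in 5 of 12 genes (0.81, adjusted p = 0.00617, and 0.141 with an estimated correlation) and lower over the light period in 8 of 12 (-1.62, 0.00167 and 0.114). Tau class glutathione transferases rose from 12 to 24 h of light in 3 of 11 genes (0.82, 9.04e-05 and 0.0102), GSTU27 from 101 to 480.4.

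Intensities of genes of the mitochondrial genome fell during stratification, in 8 of 16 genes between 12 and 48 h (mean -1.09, adjusted p = 4.43e-04, and 0.197 with an estimated correlation), with cox2 at 590.2, then 80.96, and 8.16 at 48 h of light. The values were normalized between arrays, so a loss of these transcripts cannot be told apart from a smaller mitochondrial share of the labelled RNA. The ATG8 family of autophagy fell over stratification in 7 of 9 genes, with 1 higher (-1.49, 0.0226 and 0.349), and organelle RNA editing factors rose in 3 of 13 (0.72, 0.0304 and 0.349). Smaller list differences, each lost with an estimated correlation, were those of isocitrate and succinate dehydrogenases at 12 h of stratification (0.37, adjusted p = 0.0251, and 0.197), expansins at 1 h of light (0.18, 0.0251 and 0.141), UDP-glycosyltransferases at 24 h of light (0.26 with a negative median of under 0.01 in size, 0.0293 and 0.349), and SWEET transporters (0.23, 0.0279 and 0.141) and LSM proteins (-0.52, 0.0304 and 0.416) at 48 h of light.

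The loss of 73 transcripts between harvest and dry seed, with 0 gained by limma (2511 had an unadjusted p under 0.05 in either direction), was weighed first. The 73 had a median difference of -1.94, but they were picked for their fall, so their contrast with uncalled probe sets was fixed by that choice. Their means at harvest ran from 28.7 to 3595. The 8526 other probe sets in that wide range had a median difference of -0.0084, with quartiles of -0.11 and 0.083. General decay could not be tested by this, because the values were already normalized between arrays and a decay shared by most transcripts would not show. Scaling of the arrays is argued against, as their medians shifted by only 0.009 on the log2 scale between these 2 groups. Rescaling thus had little to correct, and it left at least 74. A candidate explanation is RNA of mature pollen in the freshly harvested samples, a cell type the labels do not name: of 50 genes written down for it 16 could be followed, and their difference as a list had a mean of -0.26 and a median of -0.05 (camera, adjusted p = 2.39e-06, and 0.00179 with an estimated correlation), with 2 of them called lower, PLIM2a from 81.5 ± 10.5 to 6.45 ± 0.376 and AT59 from 28.7 ± 2.496 to 6.33 ± 0.96. It stays open, because abundant pollen genes such as ACT12 (5.32) and ANX1 (5.67) were near the floor at harvest, only 4 of the 16 were above an intensity of 50 there, 4 were above it in a group in light and 2 are in the tubulin list (TUA1 at 220 and TUB9 at 257), and of a tapetum list only EXL5 (11.2) and A9 (5.66) were named. The drying itself, which the design names, was not tested separately.

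The 387 probe sets with their transient peak at 12 h of stratification were weighed next. That 1 array made the peak is argued against, as at least 377 were found without any single array of that group. Seeds short of oxygen while imbibed in the dark may account for part of the rise into 12 h: of 42 genes written down for low oxygen 21 were named, 3 of these had been named in the report and were left out, and the other 18 were higher at 12 h than at 1 h by a mean of 1.04 and a median of 0.56 (camera, adjusted p = 5.97e-08, and 0.165 with an estimated correlation). Called higher were 7, among them AT4G39675 from 249 ± 37.8 to 3249.8 ± 110.4 and HRA1 from 8.11 ± 0.966 to 120.2 ± 1.58, while PDC2, of fermentation, went from 3207 ± 96.8 to 4471 ± 131 and was not called. The fall after 12 h is not accounted for, since from 12 to 48 h the list was not called (mean -0.40, 5 lower and 3 higher, adjusted p = 0.305), and at 48 h 9 of 18 were higher than in dry seed and 3 lower (mean 0.77, adjusted p = 0.0917). Of the 18 genes 15 were above an intensity of 50 in a group in light, so they are not specific to this time, no oxygen value was used here, and cold and dark are the same for all groups of stratification. The list also moved in light. By camera it was higher at 1 h (mean 0.43, adjusted p = 0.00867) and 12 h (0.44, 0.0153) and lower at 48 h (-1.23, 1.47e-04), each against the group before. The medians were 0.01, 0.40 and -1.36. At 1 h a few genes thus set the mean, with 3 of 18 called higher and 0 lower. With an estimated correlation the camera tests at these times had adjusted p = 0.692, 0.692 and 0.521.

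Plastid-encoded transcripts, higher at 1 h of stratification than in dry seed, were the third pattern. The 43 photosynthesis genes among them rose by a mean of 0.64 (adjusted p = 4.86e-05, and 0.661 with an estimated correlation) and 21 for gene expression by 0.63 (7.51e-04 and 0.633), after having had lower means in dry than in fresh seed (-0.44 and -0.54). The arrays of those 2 groups overlapped, with centred log2 means of the 69 plastid probe sets of 0.06 to 1.20 in fresh and -0.82 to 1.32 in dry seed. A plastid share that varies between RNA samples of one group is a candidate explanation, as the mean of 69 plastid probe sets differed by up to 2.14 between the arrays of dry seed and 1.40 between those of 1 h, against 0.62 between the groups. RNA degradation cannot be told apart, since the mean 3' to 5' difference of the controls shifted by 0.11, more than the SD of 0.059 in dry seed and less than that of 0.17 at 1 h. No biological explanation was tested for this pattern.

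Exchanging labels between the 6 arrays of a comparison gives 10 splits, too few for a share under 0.05. In each of the 11 comparisons 1 split, the real one, gave as many changed probe sets. For dry against freshly harvested seed the real split gave 73 and the highest other 55, at 1 h of stratification 117 and 43, at 12 h 857 and 2, at 48 h 4186 and 0, at 1 h of light 179 and 0, at 6 h 1974 and 0, at 12 h 987 and 0, at 24 h 1642 and 1, at 48 h 1739 and 3, over stratification 4846 and 0, and over the light period 7218 and 0. Among 100 draws of the labels of all arrays, the real one included, 1 gave as many transiently higher probe sets as the 2431 found, with 1536 as the highest other. For the 501 transiently lower probe sets 2 of 100 did, and the other of these gave 1436. Both shares are under 0.05, but as a draw can call far more than the real labels, neither is taken to exclude chance. Such draws mix arrays of all groups, so they test for any difference between groups and not for a course in time. A draw that calls several times the real number points to a structure of the samples, which was not tested.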
